A study of Arabidopsis thaliana with 6 samples.

How the data were processed

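Roots of Arabidopsis thaliana Col-0 were profiled on 6 one-colour Affymetrix arrays, 3 from plants given sulfate and 3 from plants given thiosulfate. Per the labels' protocols, total RNA was taken from roots with a column kit and DNase, and was amplified and labelled with the manufacturer's whole-transcript kits. Groups and replicate numbers were taken from the sample titles. The titles call the replicates biological but do not say whether they were separate cultures, so p-values measure the spread between these samples.

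The deposited values are on a log2 scale. Per the submitters' processing notes they were made with RMA in Transcriptome Analysis Console 4.0. RMA corrects the background, normalizes quantiles across arrays and summarises the probes of each transcript cluster. The RMA variant, the array's genome build and any filter are not given in the sources used here, and scanner files were not used here. The values ran from -0.20 to 13.3. Background correction and the probe summary could therefore not be varied, and no detection call or background bound was used. Slides and scan dates are not given in the sources used here, so no batch was tested. Values repeat exactly at low levels: 1284 of the genes tested had 2 equal values among the 6 arrays, and 35 had 1 identical value on all arrays of at least 1 group. No 2 arrays shared more than 191 equal gene values, so no array was a copy of another.

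Rows were named through a table that pairs probe identifiers with genes from the platform's annotation. It gives 1 gene for 16722 rows and several for 759, and does not list 20927 rows. Gene symbols were updated by gene identifier through a RefSeq gene table of assembly TAIR10.1, used only for names and neighbours, which matched 16574 rows. Rows with several genes or none were left out of the main test, and control rows among the unnamed could not be told from others. Of several rows for a gene, which 148 genes had, the one with the highest mean over the 6 arrays was used, giving 16548 genes. The naming is uneven. Of the protein-coding genes that carry a symbol of their own, 16.8% were named here, against 86.3% of those known by locus alone, so most well-studied genes are not analysed here.

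Differences were tested with limma 3.58.1 in R 4.3.3: a linear model with a group term, empirical Bayes variances without trend, two-sided, with Benjamini-Hochberg adjustment over the 16548 genes and a threshold of 0.05. A change is thiosulfate minus sulfate on the log2 scale. From 27 lists with 365 entries, written from textbook knowledge, 45 entries were named on the array. Of the lists, 5 had at least 3 measured members, 12 had 1 or 2, and 10 had none. The 5 were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over them, and again with an estimated correlation and with the rotation test fry. No list passed any of the 3. The genes named were the 12 largest changes in each direction among those past the threshold, filled up to 8 per direction by the smallest p where fewer passed; any measured member of the sulfur lists; and the 3 members with the smallest p of each other list. The tests, lists, naming rule and alternatives were fixed before the data were examined, except where stated.

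The fit was tested on 20 simulated data sets of 16548 genes made from the real means, with 200 genes changed in each. Variances were drawn at random from the distribution that limma fitted to the real ones, with normal noise. The fit recovered 63.0% of genes changed 2-fold, 97.4% of those changed 4-fold and 99.8% of those changed 8-fold, and 5.25% of all calls were false. The simulated sets follow the model that the test assumes, so the share of false calls does not check that model on the real arrays. The Benjamini-Hochberg cutoff loosens as more genes pass, so these shares hold for sets with 200 changed genes. They do not give the recovery where few genes pass, as in the real comparison. There AT1G75060, at 2.08-fold, had a limma adjusted p of 0.14. A shift of 0.5 (log2) planted in a list of 12 genes was called in all 20 sets, and with nothing planted 0.1 lists per set were called. The simulated genes were independent, while the estimated correlation of the real lists reached 0.28, in the iron deficiency list. No shift was planted in the smaller lists. The simulation therefore does not give the power of the list tests on the real arrays.

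The labels give both groups the same replicate numbers, which were not taken to pair the arrays. Alternatives tried were a further quantile normalization, median centring, filters on dim genes, other rules for several rows per gene, an intensity trend with robust prior, array weights, the replicate number as a block, leaving out each array, other thresholds, a test without shared variance, and the other list tests. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.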

Results

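Gene expression was measured in roots of Arabidopsis thaliana plants of the Col-0 wild type, the standard laboratory accession. The plants were grown in hydroponic culture under short days for 8 weeks in a medium whose sulfate had been exchanged for chloride. Sodium sulfate at 300 µM was the sulfur source of one group and sodium thiosulfate at 150 µM that of the other, with 3 arrays per group labelled as biological replicates. The molar concentrations of the salts differed, but each thiosulfate ion carries 2 sulfur atoms, so the amount of sulfur supplied was equal. Total RNA was hybridized to 1-colour Affymetrix arrays, which read each transcript cluster with a set of short probes. The comparison asks how root transcript levels differ when thiosulfate, a sulfur compound more reduced than sulfate, replaces sulfate as the sulfur source.

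The deposited table holds log2 expression values for 38408 rows on each of the 6 arrays. The median over all rows lay between 2.35 and 2.38 on the sulfate arrays and between 2.41 and 2.48 on the thiosulfate arrays. Over the 16548 genes that could be named and tested, the correlation between arrays of one group lay between 0.980 and 0.983. Between arrays of different groups it lay between 0.974 and 0.982. Arrays carry no read depth, and their number limits the precision. The median 95% interval of a gene's change reached 0.39 on the log2 scale to either side, or 1.31-fold.

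With thiosulfate in place of sulfate, 1 gene rose and 1 fell at an adjusted p of 0.05 among the 16548 tested. AT1G15540 rose from 2.16 ± 0.26 to 4.16 ± 0.26 (log2, mean ± SD, n = 3 per group), a 3.998-fold change with an SE of 0.19 on the log2 scale and a limma adjusted p of 0.0357. AGL89 (AT5G27580), a MADS-box transcription factor gene of the AGAMOUS-LIKE family, fell from 2.32 ± 0.28 in sulfate to 0.67 ± 0.09 in thiosulfate (SD, n = 3 each), a difference of -1.65 between the listed log2 values (SE 0.17, limma adjusted p = 0.0361). The thiosulfate level lay below 0.987, the median level of the dimmest of 5 equal bins of the genes tested, and no background bound was used, so this difference for AGL89 is one of listed values and not a measured fold. All 3 thiosulfate arrays lay on one side of all 3 sulfate arrays for both genes. Chance gives this separation to 10% of genes in a design of this size, and picking genes by p on the same arrays favours it.

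The next genes in rank did not pass the correction. On the higher side were AT3G17280 (log2 difference 1.41, adjusted p = 0.078), AT1G67150 (1.33, adjusted p = 0.14), AT1G75060 (1.05), AT2G28990 (1.11), AT5G02360 (1.13), LSH9 (0.997) and AT1G29270 (0.88), the last 5 with limma adjusted p-values between 0.14 and 0.20. LSH9 belongs to the family named for LIGHT-DEPENDENT SHORT HYPOCOTYLS 1. On the lower side were AT1G51010 (log2 difference -1.80), AT1G51020 (-1.47), AT1G51035 (-1.17), AT1G18830 (-1.64), AT4G00651 (-1.03), AT2G30730 (-0.87) and AT1G01355 (-0.77), with adjusted p-values from 0.20 to 0.26. AT2G30730 and AT1G01355 stood at 1.04 and 1.07 in thiosulfate, near 0.987, the median level of the dimmest bin. Their differences too are of listed values. AT1G51010, AT1G51020 and AT1G51035 lie close together on chromosome 1. In each of these 14 genes the 3 thiosulfate arrays stood apart from the 3 sulfate arrays. Picking genes by the smallest p on the same arrays favours such separation, so it is no further evidence. AT2G28990 and AT5G02360 were the brightest of the higher set, at 6.05 ± 0.10 and 5.84 ± 0.13 in thiosulfate (SD, n = 3) against 4.93 ± 0.20 and 4.71 ± 0.25 in sulfate.

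**Figure D1:**
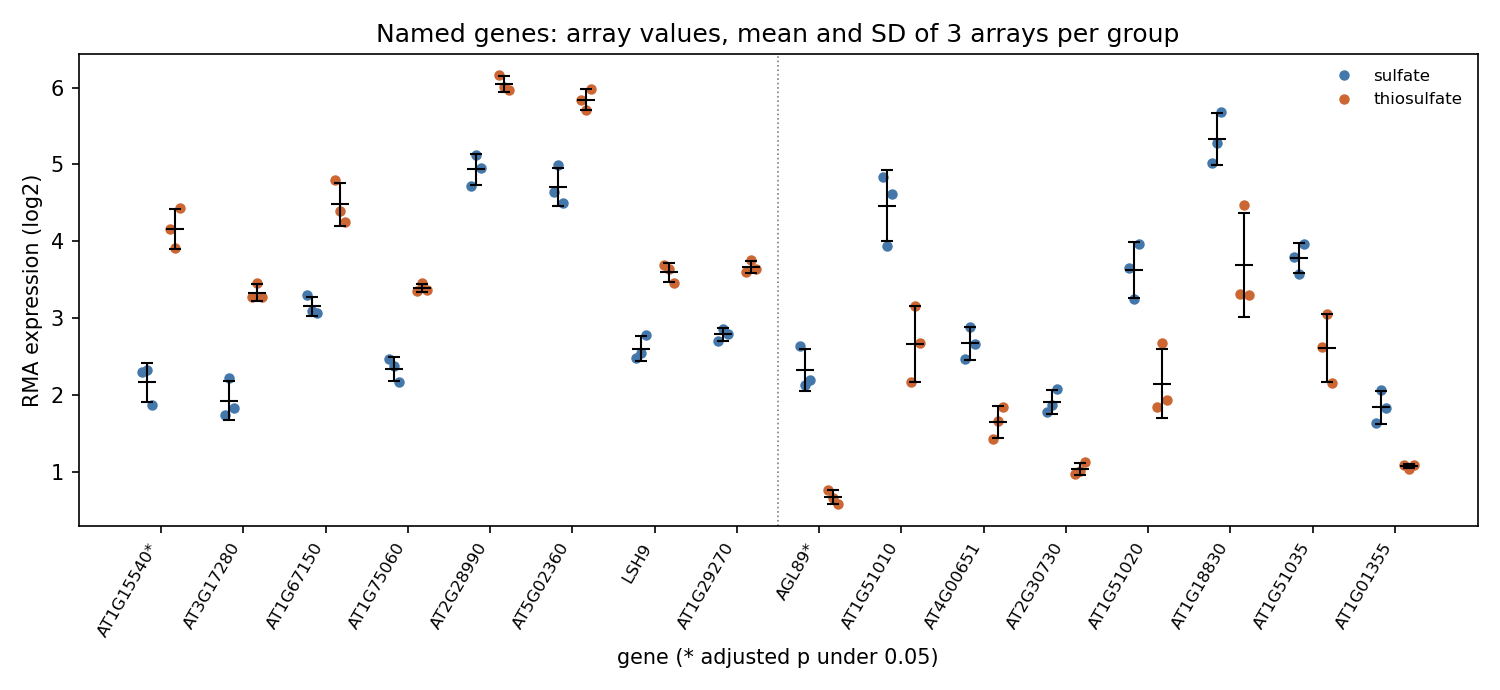
RMA expression on a log2 scale (y axis) of 16 named genes (x axis) on the 3 sulfate arrays (blue) and the 3 thiosulfate arrays (orange), with a bar for the mean and whiskers for the SD; a star marks AT1G15540 and AGL89, which passed an adjusted p of 0.05. The groups do not overlap for any of the 16 genes, which the choice of genes by p on these same arrays favours. AGL89 in thiosulfate, at 0.67 ± 0.09, is the dimmest value shown.

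Without correction for multiple testing, 1660 genes (10.03%) had a limma p under 0.05, where chance alone gives 827.4, and 892 of them lay higher and 768 lower in thiosulfate. That split depended on the scaling: after a further quantile normalization it was 635 higher and 1050 lower. A difference of at least 2-fold was seen in 97 genes, 68 higher and 29 lower. For 92.7% of genes the 95% interval of the listed values excluded a difference of 2-fold in either direction. Dim genes are among them, and no background bound was used. For dim genes a narrow interval therefore does not exclude a 2-fold change in transcript level.

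None of the measured genes of sulfur metabolism passed the correction over all genes. For SIR, CBL, UGT74B1 and STR17 the groups did not overlap, a separation that chance gives to 10% of genes in this design. These and STR18 had an unadjusted limma p under 0.05, as did 10.03% of all genes tested. Only 20 genes of the sulfur lists could be named on the array. No member of the sulfate transporter, cysteine and glutathione or sulfur regulator lists was among them, so these were not analysed here. SIR, the single sulfite reductase of the plant, was 1.49-fold higher in thiosulfate (7.005 ± 0.13 against 7.58 ± 0.29, SD, n = 3; 95% interval of the log2 difference 0.18 to 0.98), with an adjusted p of 0.34 by limma over all genes. Among the 3 measured genes of sulfate activation and reduction it was the 1 that passed when adjusted over the list alone. APS3 and APS4, which encode ATP sulfurylases, had log2 differences of 0.23 (95% interval -0.18 to 0.64) and 0.06 (-0.43 to 0.55), the latter turning to -0.019 after a further quantile normalization. The list as a whole did not pass the camera test (adjusted p = 0.11, and adjusted p = 0.38 with an estimated correlation).

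The sulfurtransferase list was measured best, with 12 of 22 members, but STR1, STR2 and STR16 were not among them. Nor were ETHE1 and SOX, the list's genes of persulfide and sulfite oxidation, so these were not analysed here. Of the 12 members measured, 6 lay higher and 6 lower. TROL, AT2G40760 and AT5G19370 of the higher ones turned lower after a further quantile normalization and CaS after median centring. None passed over all genes or adjusted over the list alone. STR17 (AT2G17850), a rhodanese-domain gene and the brightest of the 12, was 1.52-fold higher in sulfate (9.10 ± 0.23 against 8.49 ± 0.13, SD, n = 3; log2 difference -0.61, limma adjusted p = 0.31), and the groups did not overlap. STR18 was 1.58-fold higher in sulfate (log2 difference -0.66, 95% interval -1.21 to -0.10, limma adjusted p = 0.42) with overlapping groups. STR4A (AT3G25480) had a log2 difference of -0.44 and STR19 (AT2G21045) one of 0.24. The other 8 members lay between -0.28 and 0.24. The list's median was -0.07, its mean -0.14, and its camera adjusted p was 0.28 (adjusted p = 0.38 with an estimated correlation).

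Of the remaining sulfur genes, UGT74B1, a glucosyltransferase that makes desulfoglucosinolates, the precursors of glucosinolates, was 1.85-fold higher in thiosulfate (3.82 ± 0.44 against 4.71 ± 0.21, SD, n = 3; 95% interval of the log2 difference 0.38 to 1.40, limma adjusted p = 0.31). UGT74C1 (AT2G31790), its counterpart in aliphatic glucosinolate synthesis, had a log2 difference of 0.22 (95% interval -0.24 to 0.67). CBL, cystathionine beta-lyase of methionine synthesis, was 1.27-fold higher in thiosulfate (5.74 ± 0.05 against 6.08 ± 0.09, SD, n = 3; limma adjusted p = 0.44). Each of these 3 was the only measured member of its list, so adjustment over the list alone left the unadjusted p: 0.0034 for UGT74B1 and 0.031 for CBL by limma, and 0.31 for UGT74C1. Among the sulfur deficiency markers, SDI2 (AT1G04770) had a log2 difference of 0.25 (95% interval -0.13 to 0.62). BGLU28 had one of -0.09 (-0.39 to 0.21), at a low level of 1.37 in sulfate. All 3 thiosulfate arrays and sulfate replicate 2 were listed at the same 1.28. Neither SDI2 nor BGLU28 passed over all genes or adjusted over the list alone.

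**Figure D2:**
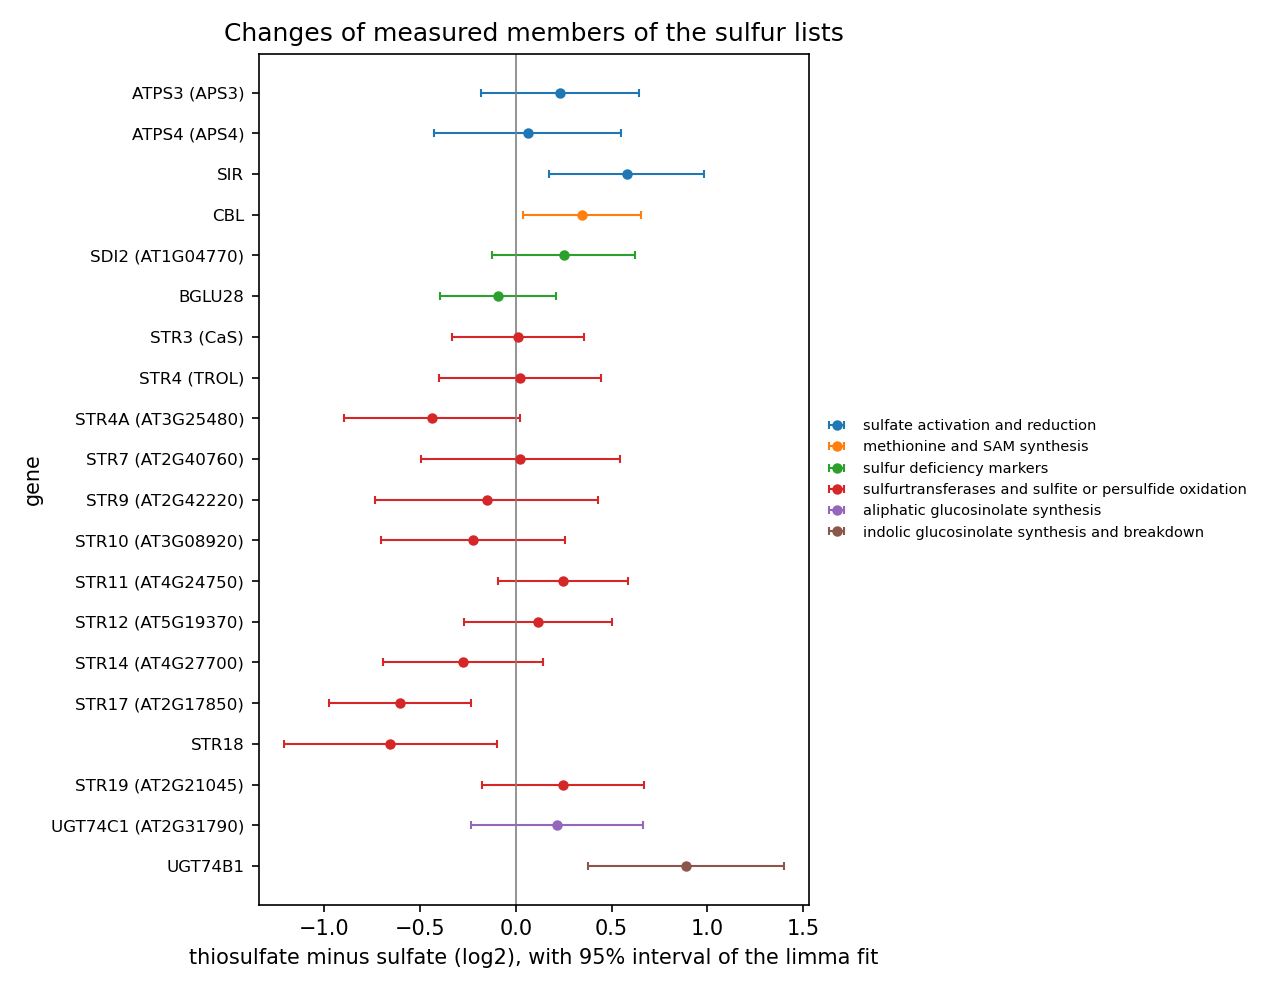
Log2 difference between thiosulfate and sulfate (x axis, thiosulfate minus sulfate) of the 20 measured genes of the sulfur lists (y axis), with points for the estimate and bars for the 95% interval of the limma fit, coloured by list. The interval lies above 0 for SIR, CBL and UGT74B1 and below 0 for STR17 and STR18, and none of the 20 genes passed an adjusted p of 0.05 over all genes.

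Of the 25 members of the iron deficiency list 5 were measured, and IRT1, FRO2 and FIT were not among them. All 5 had lower means in thiosulfate, but none passed over all genes or adjusted over the list alone. The list did not pass the camera test (adjusted p = 0.095, and adjusted p = 0.38 with an estimated correlation). S8H (AT3G12900), named after its values were seen, had a log2 difference of -0.41 (95% interval -1.62 to 0.79). This difference rested on 1 array. Thiosulfate replicate 3 stood at 4.873, while the other thiosulfate arrays lay above the sulfate mean of 6.71. IMA2 (AT1G47395), which encodes a peptide that promotes iron uptake, had a log2 difference of -0.70 (95% interval -1.32 to -0.08), and its values on the thiosulfate arrays spread widely (5.72 ± 0.63 against 6.42 ± 0.05 in sulfate, SD, n = 3). The related IMA1 (AT1G47400) had one of -0.33 (95% interval -1.01 to 0.35) and BHLH101, a transcription factor of the iron response, one of -0.30 (-0.66 to 0.06). BHLH101 was dim, at 1.45 in sulfate and 1.15 in thiosulfate. The list passed only in 2 of the fits with 1 array left out: without thiosulfate replicate 2 its mean was -0.57 with a camera adjusted p of 0.0105, and without sulfate replicate 1 it was -0.46 with a camera adjusted p of 0.0475. Over all alternatives its adjusted p ran from 0.0105 to 0.441.

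No member of any other list passed over all genes. In the oxidative stress list all 3 measured members lay lower (UPOX, AT2G21640, log2 difference -0.48; GSTU25 -0.27; GR1, a glutathione reductase, -0.03; camera adjusted p = 0.28, and adjusted p = 0.38 with an estimated correlation), with none passing adjusted over the list alone. In the abscisic acid and osmotic list 3 of 5 members lay higher and 2 lower (COR15A -0.31, KIN2 0.26 with a 95% interval of -0.27 to 0.79, and COR47 0.21), again with none passing adjusted over the list alone, and with a camera adjusted p of 0.88 (adjusted p = 0.89 with an estimated correlation). COR15A was listed at 0.71 in thiosulfate, as dim as AGL89 there, so its difference too is one of listed values. The mean of that list was 0.026, and -0.0036 after a further quantile normalization. Of the hypoxia list, PDC2, a pyruvate decarboxylase, was 1.35-fold higher in sulfate (6.28 ± 0.10 against 5.85 ± 0.14, SD, n = 3) and was the 1 of 2 measured members that passed adjusted over the list alone. The other, HRA1 (AT3G10040), had a log2 difference of -0.17. PDF1.2 of the jasmonate list, dim at 1.06 in sulfate and 1.21 in thiosulfate, had one of 0.15. HSP22 (AT4G10250, listed as ATHSP22.0) of the heat shock list had one of -0.35 (95% interval -0.94 to 0.23). AKINBETA1 of the sugar starvation list had one of -0.21 (-0.59 to 0.17), and GI of the circadian clock one of -0.15.

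Markers of cell types were few. For the root hair, EXPA18 and EXPA7, both expansins, had log2 differences of 0.31 and 0.25, and for dividing cells AUR2 and AUR1, both Aurora kinases, had 0.21 and 0.01. AUR1 turned to -0.090 after a further quantile normalization and to -0.0029 after median centring. The green tissue genes LHCB4.1, a light-harvesting protein, and RCA, Rubisco activase, had log2 differences of -0.21 and -0.09. None of these 6 passed over all genes or adjusted over the list alone. No member of the endodermis, suberin, xylem or phloem lists, nor of the phosphate, nitrate or salicylate lists, was named on the array, and these were not analysed here.

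With 1 array left out, the log2 differences stayed between 1.85 and 2.13 for AT1G15540 and, as listed, between -1.75 and -1.50 for AGL89, but most of these fits of fewer arrays called neither. No gene passed in 5 of the 6 limma fits (smallest adjusted p 0.125, 0.0544 and 0.201 without sulfate replicates 1, 2 and 3, and 0.236 and 0.180 without thiosulfate replicates 1 and 3), and without thiosulfate replicate 2 AT1G15540 (adjusted p = 0.0486) passed but AGL89 (adjusted p = 0.0916) did not. AT4G29905, chosen after its values were seen, also passed there. When every row of the table was tested, named or not, 0 of 38408 passed a limma adjusted p of 0.05 and 3502 had an unadjusted p under 0.05.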

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

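The tests in this part were chosen after the result was seen. The 13951 unnamed rows with values of their own, which the comparison of named genes does not use, had a higher median on every thiosulfate array than on any sulfate array: 3.33 to 3.48 against 3.28 to 3.32 (log2), a difference in means of the array medians of 0.0958. The median over the named rows, each distinct set of values counted once, overlapped between the groups, at 2.38 to 2.41 in thiosulfate and 2.36 to 2.41 in sulfate. The third set held 6976 unnamed rows that share their values with another row, in 1537 distinct sets of values. Over these 1537 the array medians also overlapped, narrowly, at 1.465 to 1.578 in thiosulfate and 1.398 to 1.467 in sulfate. The median difference was 0.11 over the distinct sets of values and 0.13 over all 6976 rows. Array medians over all 6976 rows were not computed. Chance separates 3 arrays from 3 in 10% of cases, and 3 sets of rows were looked at. In the 13951 rows the median difference within each row was 0.018. Of 15488 distinct unnamed rows, 0 passed a limma adjusted p of 0.05; 1451 had an unadjusted p under 0.05, of which 907 lay higher and 544 lower in thiosulfate. No explanation was tested for this.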

How the results depend on the processing

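One alternative, testing each distinct row once, was chosen after seeing the data. The count of 2 genes (1 higher, 1 lower) was found again, with both AT1G15540 and AGL89, after a further quantile normalization, median centring, a mild filter on dim genes (12411 kept), averaging rows, an intensity trend with a robust prior, and array weights. With a stricter filter (8274 genes kept), 1 gene passed and 0 lower ones, since AGL89 was filtered out. Testing every row gave 0 genes (3502 rows at an unadjusted p under 0.05), testing every distinct row gave 0 (3131), and a test with no shared variance gave 0 (1297 genes). At an adjusted p under 0.1, 3 genes passed, 2 higher and 1 lower; at an unadjusted p under 0.05 with a 2-fold change, 95 did, 67 higher and 28 lower. With the replicate number as a block 0 genes passed by limma, 0 higher and 0 lower (1717 at an unadjusted p under 0.05), with both genes at an adjusted p of 0.11. Deviations of same-numbered arrays from their group means correlated at 0.056, -0.025 and -0.032, and 2 of 3 sulfate arrays correlated better with another number, so this loss is not read as a weaker effect. Leaving out each array gave 0 to 2 genes, 0 to 2 higher and 0 lower; over all limma alternatives per gene the adjusted p of both ran from 0.0200 to 0.236. The share of higher calls at an unadjusted p moved from 892 higher and 768 lower to 635 and 1050 after quantile normalization and to 708 and 318 with the stricter filter; the median change of all genes was -0.016, -0.047 and 0.047 in these fits. No list passed in any alternative with all arrays. With 1 array left out the iron list's mean ran from -0.57 to -0.14 and passed in 2 fits, given above, and that of the abscisic acid list from -0.075 to 0.12; the latter was -0.0036 after quantile normalization. After quantile normalization these signs turned: APS4 -0.019, AT5G19370 -0.0030, TROL -0.085, AT2G40760 -0.073 and AUR1 -0.090; after centring, CaS -0.0030 and AUR1 -0.0029. With 1 array left out these log2 differences crossed 0: APS4 -0.10 to 0.27, AT2G42220 -0.47 to 0.082, TROL -0.18 to 0.12, AT2G40760 -0.13 to 0.27, CaS -0.064 to 0.12, GSTU25 -0.72 to 0.038, GR1 -0.12 to 0.046, PDF1.2 -0.029 to 0.29, AT3G10040 -0.32 to 0.026, LHCB4.1 -0.57 to 0.10, EXPA18 -0.018 to 0.51, AUR2 -0.015 to 0.37 and AUR1 -0.19 to 0.27. Others came near 0: IMA1 -0.63 to -0.044, AT3G08920 -0.38 to -0.026, HSP22 (ATHSP22.0) -0.61 to -0.049, AKINBETA1 -0.30 to -0.048, KIN2 0.026 to 0.43 and COR47 0.057 to 0.39. So did AT5G19370 at 0.034 to 0.25, RCA at -0.14 to -0.052, EXPA7 at 0.064 to 0.54 and BGLU28 at -0.14 to -0.063. GI ran from -0.29 to -0.070, UGT74C1 (AT2G31790) from 0.072 to 0.36 and APS3 from 0.096 to 0.33. UPOX (AT2G21640) kept its sign at -0.78 to -0.28, as did IMA2 (AT1G47395) at -1.05 to -0.43. Where no reason is given, the cause was not tested. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. Counts in brackets are of splits that reached the real one's value, the real one included. The real split gave 2 genes at the adjusted threshold and the highest other split 1 (1 of 10). The larger direction held 1 and 1 (2 of 10). At an unadjusted limma p under 0.05 it was 1660 genes against 1010 (1 of 10). Lists with an unadjusted camera p under 0.05 numbered 2 against 2 (3 of 10).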

Other observations

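The sets of genes in this part were chosen after the data were seen, and the tests of the AT1G51010 group and of green tissue after their results were. Genes encoded in the plastid genome lay higher in thiosulfate as a set. Of the 63 measured, 59 lay higher and 4 lower, with a median log2 difference of 0.26. The largest were rbcL, the large subunit of Rubisco (9.07 ± 0.31 in sulfate and 9.52 ± 0.13 in thiosulfate, SD, n = 3, log2 difference 0.46), psbB (0.43) and petB (0.43) of the photosynthetic membrane complexes, and psbE (0.42); atpA, a subunit of the plastid ATP synthase, had the smallest p (log2 difference 0.39). By limma 0 of the 63 passed the correction over all genes and 11 had an unadjusted p under 0.05. Camera with its preset correlation gave an adjusted p of 1.6e-10 over 26 sets formed from symbol stems and gene location, and adjusted p = 0.73 with an estimated correlation. The rotation test fry of limma, which asks only whether the set moves one way and was not adjusted, gave a p of 0.0317. The set's median on each array lay at 8.63 to 8.84 in sulfate and 8.92 to 9.04 in thiosulfate, which as a single value of 3 against 3 arrays cannot give an exact two-sided permutation p below 0.1. Of the 26 sets 2 passed the preset test, the other being genes with the symbol stem IQD (adjusted p = 0.0342, and adjusted p = 0.729 with an estimated correlation), and 0 passed with an estimated correlation.

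The named nuclear genes nearest in level did not share the shift as a set. For each plastid gene 1 of its 40 nearest nuclear genes was drawn. Of 10000 such random lists 0 reached the set's median, and the lists centred on -0.0059 (permutation p = 1e-04, the smallest they can give). Few genes were that bright: STR17, at 9.10 in sulfate and 8.49 in thiosulfate, already stood at percentile 99.4 of mean level. The lists therefore drew repeatedly on few genes, and the brightest plastid genes may have been matched with dimmer ones. This argues against an offset shared by the nuclear genes drawn, and does not test an offset of the brightest rows alone. The p-value is over draws of single genes, not over arrays, and takes no account of correlation among plastid genes. The values also argue against 1 array alone, since the lowest median with 1 array left out was 0.2037. After a further quantile normalization of all 6 arrays the median fell from 0.265 to 0.18, with 54 genes higher. Part of the shift therefore depended on the scaling, and an offset of that size stays open. LHCB4.1 and RCA both lay lower (log2 differences -0.21 and -0.09, and -0.33 and -0.21 after quantile normalization), which goes against a larger share of green tissue, as does the upper 95% bound of RCA, 0.215, below the plastid median. That of LHCB4.1, 0.456, is above it and keeps this explanation open. A higher plastid transcript content with thiosulfate is a hypothesis that these 6 arrays leave open, next to a difference in RNA preparation, which was not tested.

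AT1G51010, AT1G51020 and AT1G51035, each lower in thiosulfate by at least 1.17 on the log2 scale, are neighbours on chromosome 1, and AT1G51030 between them had a log2 difference of -1.06 (limma unadjusted p = 0.029). The genes on either side, AT1G51000 and AT1G51040, had 0.01 and -0.14, at levels between 1.25 and 1.40 that leave little room to fall. The nearest brighter genes tested, AT1G50970 (4.83 in sulfate and 4.66 in thiosulfate) and bHLH115 (6.06 and 6.15), had -0.16 and 0.09. Of 1000 shuffles of gene order 1 gave as many windows of 5 neighbouring genes with 3 at a p under 0.001 on the same side (permutation p = 0.002). The window and threshold were set after this group was seen, and without its 3 genes 0 of the 2 windows are left, so chance placing stays open. Overlapping gene models are excluded in the gene table, where 0 of the pairs among the 3 overlap, though the table's assembly may not be that of the array. Probes that match more than 1 of these genes, a transcript running through them, or a local difference between the plants are candidate explanations that were not tested here, and none of the 4 genes passed the correction over all genes. Across all 16442 placed genes, changes of adjacent genes correlated weakly (Spearman's rho 0.041 over genes, which are not independent replicates; permutation p = 0.001, the smallest that 1000 shuffles can give).

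Dim genes lay slightly lower and bright genes slightly higher in thiosulfate. Over 5 equal bins of mean level the median log2 difference was -0.065, -0.095, 0.0013, 0.060 and 0.039 from the dimmest to the brightest. These medians are of the same order as shifts from scaling, though the median over all genes shifted by less than most of them. A further quantile normalization moved the median over all genes from -0.016 to -0.047. It moved RCA from -0.093 to -0.21 and the dim CaS from 0.011 to 0.053. The bins were not computed again there, so whether the pattern depends on the scaling was not tested.

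Among unnamed rows, the 2 with the smallest p in each direction had probe identifiers 13320465 (log2 difference 1.92, limma adjusted p = 0.104) and 13322587 (1.304), and 13455624 (-2.88) and 13537500 (-1.44), the last 3 with a limma adjusted p of 0.212. The levels of 13322587 in sulfate (0.62) and of 13455624 in thiosulfate (0.41) were as dim as that of AGL89, so these are differences of listed values. Their genes are not named here.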
